A study of Mus musculus with 30 samples.

How the data were processed

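Gene expression was measured on 30 mouse oligonucleotide arrays (Affymetrix Mouse Genome 430 2.0, 1 colour, biotin-labelled total RNA, per the labels). The cells were mouse embryonic fibroblasts without Myod1 and Myf5, which carried a retrovirus for a MyoD protein fused to the estrogen receptor (ER-MyoD wt), for the same fusion with lysines 99, 102 and 104 replaced so that they cannot be acetylated (ER-MyoD RRR), or an empty retrovirus. The cells were then kept in differentiation medium with beta-estradiol, which switches on the fusion protein. The titles gave 10 groups of 3 arrays: ER-MyoD wt at 0, 6, 12 and 24 h, and ER-MyoD RRR and empty retrovirus at 6, 12 and 24 h each. No 0 h arrays of ER-MyoD RRR or empty retrovirus were analysed here, so a change from 0 h in ER-MyoD wt holds medium, hormone and MyoD together. A difference of cell preparation at 0 h may enter as well and was not tested. The labels do not say that the 3 replicates of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

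The deposited values were 1 linear signal intensity per probe set and array, from 0.0474 to 20986. The software and scaling behind them are not given in the sources used here. From the values, the mean of each array without the highest and lowest 2% of its probe sets was 150, so the deposited intensities had been scaled between arrays. Array medians ranged from 38.0 to 64.1. The number of arrays limits the precision of every value.

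Of 45101 probe sets, 64 controls were left out. The platform annotation gave 1 gene symbol for 34945 of the other 45037 probe sets, several for 932 and none here for 9160. Symbols were looked up by Entrez id in the gene table, which held 34741 of them and changed 0 names. A gene was represented by the probe set with the highest mean over all arrays among those with 1 symbol, which left 18193 genes, 9010 of them with more than 1 probe set. The values entered the tests as log2(signal + 16) after quantile normalization over the 45037 probe sets, with no filter on low values. A log2 difference is therefore on that scale and understates the change of a gene with low signal. Symbols of the annotation may be old.

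A linear model with 1 mean per group was fitted to all 30 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the spread on the mean), which left 20 residual degrees of freedom. It gave 12 comparisons of 2 groups and 1 test of whether the ER-MyoD RRR minus ER-MyoD wt difference changed from 6 h to 24 h. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 18193 genes within a comparison, and a gene passed at an adjusted p under 0.05. Each error given as ± beside a log2 difference is the standard error of that model, with n = 3 arrays per group. Tables were read with the data.table package (1.17.8), and plots were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

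A set of 26 gene lists was fixed before the data were examined. They covered myogenic regulators, the sarcomere, the acetylcholine receptor and neuromuscular junction, calcium handling, muscle energy metabolism, myoblast adhesion and fusion, the dystrophin complex and costamere, the Notch pathway and Id inhibitors, cell cycle exit, proliferation, extracellular matrix and fibroblast markers, serum response genes, interferon response, estrogen-responsive genes, acetyltransferases, deacetylases and partners of MyoD, p53 targets, cholesterol synthesis and uptake, the unfolded protein response, and smooth muscle markers. The other lists held markers of cells that the cultures could contain or become: cardiac, adipocyte, chondrocyte and osteoblast, neuronal and glial, macrophage and blood, endothelial, and epithelial. Lists were compared with all other genes by limma's camera with a preset correlation between genes of 0.01, adjusted over all lists and comparisons of a family (ER-MyoD RRR minus wt, wt minus empty, RRR minus empty, wt against 0 h, and the change from 6 h to 24 h). Camera with an estimated correlation and fry were alternatives. For members of a list, the number past the threshold is given over all genes and adjusted over the list alone.

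MyoD-responsive genes were those at least 2-fold different and past the threshold in ER-MyoD wt minus empty retrovirus at another time (24 h for the tests at 6 and 12 h, 12 h for the test at 24 h), so that the arrays which chose them were not those compared. They can include genes that differed between these cells before the medium change, since no empty retrovirus array at 0 h was analysed.

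The genes named were taken by a rule fixed at the same stage: Myod1 and Myf5, the 8 largest rises and 8 largest falls of each ER-MyoD RRR minus wt comparison and of wt minus empty at 24 h among genes past the threshold whose arrays did not overlap, fewer of the other comparisons, up to 4 members of each list with the smallest p, and 16 fixed genes of myogenesis in each ER-MyoD RRR minus wt comparison. Genes without a proper symbol were counted but not named. The genes that differed at all 3 times, or lay further from empty retrovirus in ER-MyoD RRR, were not part of this rule, and names among them were chosen after their values were seen.

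The fits and the list test were tested on simulated data built from the ER-MyoD RRR and wt arrays at 24 h, with 200 of 18193 genes changed. The simulated comparison found 3 of 67 genes changed 1.5-fold, 25 of 67 changed 2-fold and 58 of 66 changed 4-fold, with 4 false calls among 90. With no change it made 0 calls. A list shifted by 0.5 on the log2 scale was called and 0 of the others were. The simulated genes were independent, so this does not measure false list calls among correlated genes.

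The alternatives were the replicate number as a block, a fit of only the groups compared, 2 filters on low values, median centring of each array, offsets of 1 and 64, the mean of all probe sets of a gene, all probe sets tested separately, eBayes without the trend or robust, array weights, a 2-fold minimum, and each array left out in turn. Chosen after seeing the data were the fit without the 3 arrays that stood apart, the values with no normalization beyond the deposited scaling, lists under other scalings, and lists in the change from 6 h to 24 h. Against quantile normalization, median centring moved the median log2 difference of all genes by 0.105 in ER-MyoD wt minus empty retrovirus at 6 h and by 0.111 in ER-MyoD RRR minus empty retrovirus at 12 h. No other comparison moved by more than 0.1 under it or as deposited.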

Results

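RNA was profiled from mouse embryonic fibroblasts that lacked Myod1 and Myf5, the genes for 2 transcription factors that commit cells to skeletal muscle. The cells carried a retrovirus for wild-type MyoD fused to the estrogen receptor (ER-MyoD wt), for the same fusion with lysines 99, 102 and 104 made non-acetylatable (ER-MyoD RRR), or an empty retrovirus. The 30 arrays fell into 10 groups of 3: ER-MyoD wt at 0, 6, 12 and 24 h in differentiation medium with beta-estradiol, and ER-MyoD RRR and empty retrovirus at 6, 12 and 24 h each. Signals of 18193 genes were compared, and the number of arrays limits the precision of each value. The comparisons asked which genes differed between cells with ER-MyoD and empty retrovirus cells in the first 24 h. They also asked which of these genes differed when ER-MyoD could not be acetylated on those lysines.

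Myod1 itself was measured first. Its mean signal was 1185 ± 101 (SD, n = 3) in ER-MyoD wt at 0 h and 897 ± 200, 802 ± 303 and 612 ± 149 at 6, 12 and 24 h. In ER-MyoD RRR it was 863 ± 479, 535 ± 264 and 471 ± 146, and in empty retrovirus cells 167 ± 32.0, 182 ± 11.8 and 228 ± 24.6 at the same 3 times. ER-MyoD wt exceeded empty retrovirus by 2.32 ± 0.35 on the log2 scale at 6 h (adjusted p = 1.66e-05), and ER-MyoD RRR exceeded it by 2.10 ± 0.35 (adjusted p = 7.95e-05). A second Myod1 probe set did not pass at 6 h (ER-MyoD wt minus empty retrovirus 0.87, adjusted p = 0.164 over all probe sets). Between the fusions the first probe set did not pass, with ER-MyoD RRR minus wt at -0.22, -0.61 and -0.38 at 6, 12 and 24 h (adjusted p = 0.825, 0.593 and 0.679). Myf5 had a mean signal between 201 and 494 in all groups. It was lower in ER-MyoD RRR than in empty retrovirus cells at 6 h (-0.99, adjusted p = 0.0264 over all probe sets) and 12 h (-1.11, adjusted p = 0.0152). The place of the Myod1 and Myf5 probe sets relative to the deleted parts of these genes was not known here, so neither gene checks the deletions. The first Myod1 probe set shows only that its signal was higher in the arrays of both fusions.

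Replicate arrays correlated with Pearson's r between 0.946 and 0.973, and 27 of 30 arrays correlated best with an array of their own group. The exceptions were ER-MyoD RRR 6 h replicate 2, nearest to ER-MyoD wt at 6 h, and empty retrovirus 12 h replicates 1 and 3, nearest to empty retrovirus at 6 h. ER-MyoD RRR 6 h replicate 2 also had the highest 3' to 5' signal ratios of the series, 2.44 for Gapdh and 3.61 for Actb, where low ratios mark intact RNA. It stood apart from the other arrays together with empty retrovirus 12 h replicate 1, whose median signal of 64.1 was the highest, and ER-MyoD wt 24 h replicate 3.

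**Figure D1:**
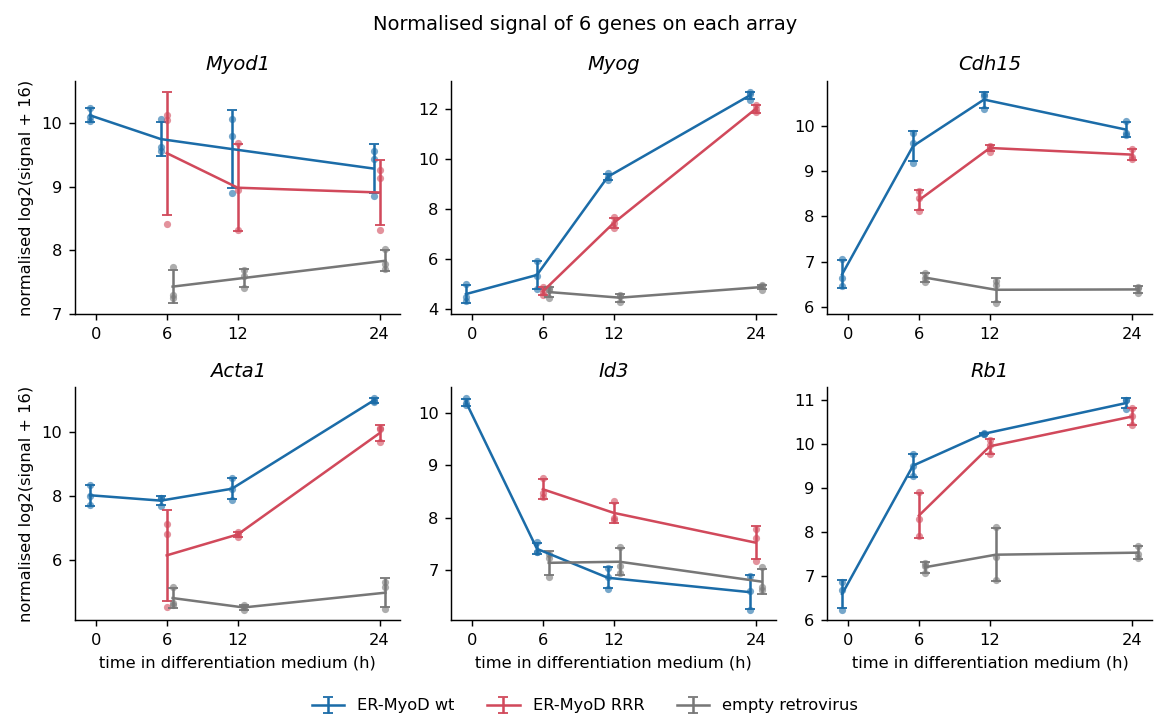
Normalised log2(signal + 16) of Myod1, Myog, Cdh15, Acta1, Id3 and Rb1 against hours in differentiation medium, with a point per array and mean ± SD of 3 arrays for ER-MyoD wt, ER-MyoD RRR and empty retrovirus. At 12 h the ER-MyoD RRR arrays lie below the wild type for Myog and Cdh15 and above it for Id3.

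ER-MyoD wt was first compared with the empty retrovirus, which shows what the fusion changed in the same medium at the same time. At 6 h single muscle and smooth muscle genes were far above the control. Tnnt2, the troponin T of embryonic muscle, had a mean signal of 4337 ± 245 against 29.1 ± 15.4 (log2 difference 6.67 ± 0.23, adjusted p = 5.69e-18). Mymk, the membrane protein needed for myoblast fusion, rose by 5.41 ± 0.26, the smooth muscle actin Actg2 by 5.25 ± 0.27 and Tagln by 4.63 ± 0.17. In ER-MyoD wt the means of Actg2 and Tagln were no higher at 6 h than at 0 h. Their gap to the control is therefore not a rise after 0 h. Cd34, a surface marker of progenitor cells, was lower by -3.64 ± 0.34, and the Wnt antagonist Dkk2 by -3.04 ± 0.25. In all, 1175 genes rose and 1127 fell, and under median centring 1364 rose and 522 fell.

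Every one of 19 measured genes of cholesterol synthesis and uptake rose at 6 h (19 adjusted over the list alone), with a median log2 difference of 2.32 (adjusted p = 5.41e-48). Among them were Fdft1 (2.92), Hsd17b7 (2.79), Sqle (2.54) and Cyp51 (2.32), enzymes of the later steps of the pathway. Of 17 smooth muscle markers 8 rose and 1 fell (10 and 1 adjusted over the list alone, median 0.493, adjusted p = 3.99e-10). Against ER-MyoD wt at 0 h this list was not higher in ER-MyoD wt at 6 h (median -0.347). Of 27 myogenic regulators 10 rose and 0 fell (12 and 1 adjusted over the list alone, median 0.293, adjusted p = 1.08e-06), Rb1, the retinoblastoma protein gene, by 2.32. Of 39 proliferation genes 18 rose and 3 fell (19 and 4 adjusted over the list alone, median 0.427, adjusted p = 9.26e-09), Aurka by 1.68. Of 17 cell cycle exit genes 9 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.619, adjusted p = 2.03e-06), Gadd45g by 2.86. Of 25 Notch pathway genes and Id inhibitors 9 rose and 0 fell (9 and 0 adjusted over the list alone, median 0.268, adjusted p = 0.000196), led by the Notch ligand Dll1 (3.08). Lists of the sarcomere, the acetylcholine receptor, fusion and the dystrophin complex were also higher (adjusted p = 0.000178, 0.000278, 0.000351 and 0.00335). The higher extracellular matrix list (median 0.408, adjusted p = 0.000619) had an adjusted p = 0.0717 with an estimated correlation. The unfolded protein response list (median 0.251, adjusted p = 0.037) had an adjusted p = 0.0643 with an estimated correlation, 0.0837 without ER-MyoD wt replicate 1 and 0.158 without empty retrovirus replicate 3.

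At 12 h myogenin, the transcription factor that follows MyoD, was well above the control. Myog had a mean signal of 613 ± 53.4 against 7.15 ± 3.48, a log2 difference of 4.82 ± 0.22 (adjusted p = 1.42e-15). Tnnt2 (7.52), Mymk (7.33), Megf10 (5.52) and the cardiac and embryonic actin gene Actc1 (5.34) led the genes that rose, and Dkk2 (-4.41), Sprr1a (-3.43), Dynap (-3.27) and Cd34 (-3.20) those that fell. In all, 1294 genes rose and 1494 fell, and under median centring 1374 rose and 817 fell. All 19 cholesterol genes were higher again (19 adjusted over the list alone, median 2.56, adjusted p = 5.33e-50), Fdft1 by 3.28 and Lss by 3.23. Of 27 myogenic regulators 15 rose and 1 fell (15 and 2 adjusted over the list alone, median 0.970, adjusted p = 5.71e-12). Of 47 sarcomere genes 15 rose and 0 fell (16 and 0 adjusted over the list alone, median 0.201, adjusted p = 2.38e-06). Of 30 serum response genes 2 rose and 13 fell (4 and 13 adjusted over the list alone, median -0.391, adjusted p = 0.00146), Fosl1 by -2.30. The cell cycle exit (adjusted p = 3.35e-07), smooth muscle (0.000216), acetylcholine receptor (0.000278) and dystrophin (0.0178) lists were higher. The fusion list (adjusted p = 0.0165) had an adjusted p = 0.154 with an estimated correlation, the calcium handling list (0.0281) one of 0.0673 and the proliferation list (0.0216) one of 0.303 with an estimated correlation. The calcium list also did not pass under median centring (0.0712), as deposited (0.0663), without ER-MyoD wt replicate 1 (0.129) or without empty retrovirus replicate 3 (0.0969), and proliferation not without that last array (0.0757).

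At 24 h the ER-MyoD wt cells expressed genes of the contractile apparatus, the acetylcholine receptor and calcium release, while genes of dividing fibroblasts were lower. Myog reached a mean signal of 6113 ± 72.8 (log2 difference 7.64 ± 0.22, adjusted p = 7.39e-20). Tnnt2 (8.78), Mymk (8.30), Chrng, the embryonic acetylcholine receptor subunit (7.69), Tnni1 (7.60), Actc1 (7.34), the myosin chaperone gene Unc45b (6.26) and Mylpf (6.15) rose most. Pdgfra, a receptor of fibroblasts and progenitors (-4.49), Dkk2 (-4.47), C1s1 (-4.32), Mfap4 (-4.23), Islr (-3.94), Efemp1 (-3.80), Dnm1 (-3.42) and Nfib (-3.41) fell most. In all, 2066 genes rose and 2538 fell.

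By list, 25 of 47 sarcomere genes rose and 3 fell at 24 h (26 and 3 adjusted over the list alone, median 1.06, adjusted p = 2.52e-13). Of 25 calcium handling genes 16 rose and 0 fell (16 and 0 adjusted over the list alone, median 0.994, adjusted p = 2.19e-09), with Hrc, a calcium-binding protein gene of the sarcoplasmic reticulum, at 5.41. Of 22 energy metabolism genes 13 rose and 0 fell (14 and 0 adjusted over the list alone, median 0.772, adjusted p = 2.22e-09), with Cox8b at 5.48 and the muscle enolase Eno3 at 4.03. The acetylcholine receptor list (9 rose, 1 fell, median 1.22, adjusted p = 2.36e-07) and myogenic regulators (15 rose, 1 fell, median 0.927, adjusted p = 1.72e-10) had the same numbers adjusted over the list alone. Of 17 cell cycle exit genes 10 rose and 2 fell (10 and 3 adjusted over the list alone, median 1.01, adjusted p = 0.0026). Rb1 rose by 3.41 and Cdkn1a, the p21 inhibitor of the cell cycle, by 2.67. Of 39 proliferation genes 0 rose and 30 fell (1 and 33 adjusted over the list alone, median -0.972, adjusted p = 1.53e-15), among them Mcm7 (-1.16), Mcm4 (-1.45) and Top2a (-1.41). Of 35 extracellular matrix and fibroblast genes 3 rose and 26 fell (3 and 29 adjusted over the list alone, median -1.06, adjusted p = 1.47e-15), among them Lox (-2.19), Dcn (-2.07) and Postn (-2.07). Of 21 unfolded protein response genes 0 rose and 12 fell (0 and 15 adjusted over the list alone, median -0.447, adjusted p = 2.46e-05). Cholesterol genes were still higher, 12 of 19 (12 adjusted over the list alone, median 0.793, adjusted p = 3.6e-07). The dystrophin list passed (adjusted p = 0.00771), the Notch list passed at 0.0209 and had an adjusted p = 0.0733 with an estimated correlation. The lower serum response list (median -0.279, adjusted p = 0.0475) had an adjusted p = 0.114 with an estimated correlation. It did not pass without ER-MyoD wt replicates 2 (0.0600) and 3 (0.0930) or empty retrovirus replicates 1 (0.0769) and 3 (0.0702).

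**Figure D2:**
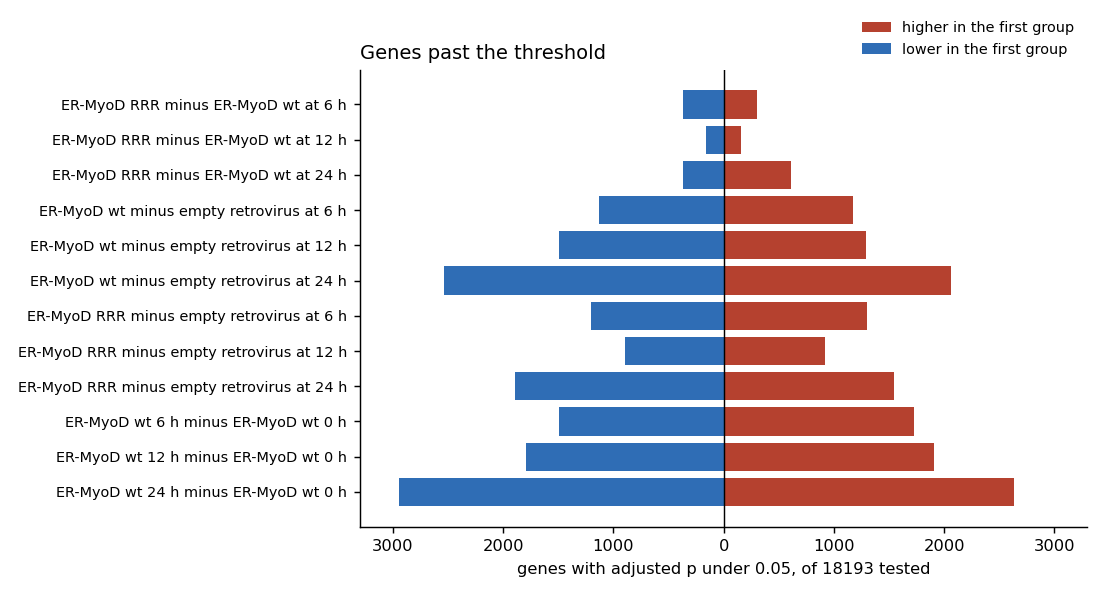
Number of genes past the threshold in each of 12 comparisons of 2 groups, with bars for genes higher and lower in the first group (n = 3 arrays per group). ER-MyoD RRR minus wt gave 668, 319 and 975 genes at 6, 12 and 24 h against 2302, 2788 and 4604 for ER-MyoD wt minus empty retrovirus, and median centring gave 254, 130 and 474 for the former.

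The main comparison set ER-MyoD RRR against ER-MyoD wt at each time. At 6 h Prune2 had a mean signal of 110 ± 41.4 against 1191 ± 465 (log2 difference -3.09 ± 0.35, adjusted p = 3.69e-06). Mycl, of the Myc family of transcription factors, was at 56.6 ± 16.9 against 356 ± 28.5 (-2.29 ± 0.25, adjusted p = 1.96e-06). Actg2 (-2.13 ± 0.27), Mymk (-2.10 ± 0.26) and Mss51 (-1.91 ± 0.34) were also lower. The stromelysin gene Mmp3, for a protease of the extracellular matrix, was higher at 3412 ± 365 against 846 ± 32.7 (1.92 ± 0.14, adjusted p = 3.22e-09). Hoxb5 (1.95 ± 0.32), Map2k6, a kinase upstream of p38 (1.84 ± 0.33), and Mmp10 (1.66 ± 0.24) were also higher. In all, 299 genes were higher and 369 lower, and 56 higher and 198 lower under median centring.

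At 6 h 9 of 26 fixed lists were lower in ER-MyoD RRR and 0 higher. Of 19 cholesterol genes 11 were lower (16 adjusted over the list alone, median -0.674, adjusted p = 3.54e-22), led by Hsd17b7 (-1.39), Idi1 (-1.25), Hmgcs1 (-1.10) and Lss (-0.93). Of 27 myogenic regulators 5 were lower (8 adjusted over the list alone, median -0.205, adjusted p = 3.02e-06), among them the LIM protein Fhl1 (-1.55), the repressor Zbtb18 (-1.47), Mef2a (-1.29) and Rb1 (-1.14). Of 17 smooth muscle markers 1 was higher and 6 lower (1 and 7 adjusted over the list alone, median -0.246, adjusted p = 0.000782). Of 14 acetylcholine receptor genes 2 were lower (4 adjusted over the list alone, median -0.482, adjusted p = 0.000627). Of 17 cell cycle exit genes 4 were lower (6 lower and 1 higher adjusted over the list alone, median -0.271, adjusted p = 0.00142). Of 47 sarcomere genes 5 were lower (6 adjusted over the list alone, median -0.0580, adjusted p = 0.0224), among them Tnnt2 (-1.67), Tnnc1 (-1.19) and Acta1, the skeletal muscle actin (-1.71). Acta1 was at 6.80, 4.52 and 7.12 (normalised log2) in ER-MyoD RRR replicates 1, 2 and 3, against 7.69 to 7.95 in ER-MyoD wt. Replicate 2, the lowest, was the array with the highest 3' to 5' ratios and weighs on that difference. The fusion list (3 lower and 1 higher, 7 and 1 adjusted over the list alone, median -0.0212, adjusted p = 0.0161) held Mymk and the adhesion protein Cdh15 (-1.19), and its adjusted p = 0.161 with an estimated correlation. The dystrophin list (2 lower, 3 adjusted over the list alone, median -0.167, adjusted p = 0.025) and the unfolded protein response list (4 lower, and 6 with 1 higher adjusted over the list alone, median -0.0970, adjusted p = 0.00324) were also lower. The median of all genes was 0.0477, so the typical sarcomere or fusion gene was little shifted. In the Notch list, which did not pass (adjusted p = 0.986), the inhibitors of MyoD activity Id3 (1.14 ± 0.19, adjusted p = 0.000656) and Twist2 (1.17) were higher and Dll1 (-0.94) lower. Id3 in ER-MyoD RRR also lay above empty retrovirus, at 8.40 to 8.76 against 6.87 to 7.30 (normalised log2). Its ER-MyoD RRR arrays lay above those of empty retrovirus at 12 h and 24 h as well.

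The 6 h count was 281 without ER-MyoD wt replicate 1, 354 without ER-MyoD wt replicate 3, and 382 without ER-MyoD RRR replicate 3. It was 106 when only these 6 arrays were fitted, where Rb1 (adjusted p = 0.0879), Acta1 (0.232) and Mef2a (0.0619) did not pass. The sarcomere list did not pass without ER-MyoD RRR replicate 2 (0.0670) or ER-MyoD wt replicate 3 (0.0634), fusion not without ER-MyoD RRR replicate 2 (0.128), and the dystrophin list not without ER-MyoD RRR replicate 1 (0.0507) or ER-MyoD wt replicate 2 (0.0775). Without the 3 arrays that stood apart, sarcomere (0.0722), fusion (0.144) and unfolded protein response (0.0520) did not pass. Of the fixed genes of myogenesis, Myog (-0.66 ± 0.22, adjusted p = 0.103), Actc1 (-0.91, 0.0710), Ccnd3 (-0.58, 0.0788), Hes6 (-0.50, 0.0884) and Cdkn1a (-0.43, 0.166) did not pass at 6 h, nor did Mef2c, Ckm, Chrna1, Myh3, Tnnt3, Mylpf and Des.

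At 12 h Myog and single genes of muscle structure were lower in the mutant. Myog had a mean signal of 158 ± 28.8 against 613 ± 53.4 (-1.84 ± 0.22, adjusted p = 6.08e-06). Lower with it were the transporter gene Slc22a4 (-2.65 ± 0.29), Actg2 (-2.58 ± 0.27), Tnnc1 (-2.06 ± 0.15), Plpp7 (-1.96) and Cryab, a small heat shock protein of muscle (-1.76 ± 0.24). Higher were Dkk2 (2.06 ± 0.25), Meak7 (1.98), Kitl, the ligand of the Kit receptor (1.81 ± 0.20), the matrix proteoglycan decorin, Dcn (1.71 ± 0.13, adjusted p = 1.1e-09), Mmp3 (1.61 ± 0.14) and Dynap (1.59). In all, 161 genes were higher and 158 lower.

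By list at 12 h, 5 of 19 cholesterol genes were lower (14 adjusted over the list alone, median -0.512, adjusted p = 3.97e-18), Lss by -1.06. Of 47 sarcomere genes 6 were lower (9 adjusted over the list alone, median -0.342, adjusted p = 4.71e-09). Of 27 myogenic regulators 5 were lower (7 lower and 1 higher adjusted over the list alone, median -0.205, adjusted p = 1.26e-05), among them Hes6 (-1.12). Of 17 smooth muscle markers 4 were lower and 1 higher (5 and 1 adjusted over the list alone, median -0.374, adjusted p = 5.67e-07), among them Tagln (-1.30). Of 14 acetylcholine receptor genes 4 were lower (5 adjusted over the list alone, median -0.398, adjusted p = 5.6e-06). The dystrophin list (1 higher and 1 lower, 1 and 2 adjusted over the list alone) was lower with an adjusted p = 0.00861. The energy list (2 lower, 4 adjusted over the list alone), with Eno3 at -0.87, was lower with an adjusted p = 0.016, and an adjusted p = 0.0643 with an estimated correlation. The p53 target list had 0 members past the threshold over all genes and 3 lower adjusted over the list alone (adjusted p = 0.0284). It did not pass under median centring (0.0833) or without ER-MyoD RRR replicate 1 (0.0550), ER-MyoD wt replicate 2 (0.0548) or ER-MyoD wt replicate 3 (0.05005). Serum response genes were higher (1 of 30, 4 adjusted over the list alone, median 0.178, adjusted p = 0.0102). Of 35 matrix genes 7 were higher and 3 lower (11 and 5 adjusted over the list alone), with Prrx1 at 1.01. Their mean of 0.160 and the test pointed up (adjusted p = 0.042) while the median was -0.005. The adjusted p = 0.290 with an estimated correlation and was 0.120 under median centring (median 0.004), 0.117 as deposited, and 0.0688 with the replicate number as a block. It was 0.183 without ER-MyoD RRR replicate 1, 0.181 without ER-MyoD wt replicate 3 and 0.0548 without ER-MyoD wt replicate 2.

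Among the fixed genes at 12 h, Id3 (1.24 ± 0.19) was higher, and Cdh15 (-1.07 ± 0.17) and Ccnd3, a cyclin of differentiating muscle (-1.08 ± 0.19), were lower, the last not with the mean of its probe sets (adjusted p = 0.145). Actc1 (-1.30) and Acta1 (-1.43) passed at 0.0120 and 0.0471 but not with an offset of 1 (0.1995 and 0.2553). Actc1 did not pass without ER-MyoD RRR replicates 1 (0.0645) or 3 (0.0557) or ER-MyoD wt replicate 3 (0.0568), and Acta1 not without any 1 of the 6 arrays, the adjusted p between 0.0609 and 0.208. Rb1 (-0.29) and Cdkn1a (-0.59, adjusted p = 0.0644) did not pass. The 12 h count of 319 was 151 without ER-MyoD wt replicate 1, 185 and 186 without ER-MyoD RRR replicates 3 and 2, 194 without ER-MyoD wt replicate 2, and 206 without ER-MyoD RRR replicate 1. It was 130 under median centring and 491 without the 3 arrays that stood apart, which lie in other groups and enter through the shared spread.

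At 24 h matrix, fibroblast and proliferation genes were higher in the mutant, and genes of calcium handling and energy metabolism were lower. Aldh1a1, a retinaldehyde dehydrogenase, had a mean signal of 379 ± 85.7 against 88.2 ± 58.7 (2.20 ± 0.41, adjusted p = 0.000883), and not with an offset of 1 (0.0582) or only these 6 arrays fitted (0.0584). Svep1, for a large matrix adhesion protein, was at 144 ± 29.2 against 20.3 ± 3.86 (2.05 ± 0.24, adjusted p = 2.09e-06). Srpx2 (1.95), Amot (1.83), Medag (1.79 ± 0.18), Cpa1 (1.72), Wdr60 (1.67) and Pdlim2 (1.67 ± 0.16) were also higher. Lmod1, an actin filament nucleator of smooth muscle (-1.99 ± 0.30), Slc22a4 (-1.82 ± 0.29), Gal3st2 (-1.64), the ubiquitin ligase subunit gene Asb2 (-1.57 ± 0.27) and Pgbd5 (-1.56) were lower. Coq8a (-1.85 ± 0.30) was lower, though not with the mean of its probe sets (adjusted p = 0.0863). In all, 608 genes were higher and 367 lower, and under median centring 175 higher and 299 lower.

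Of 35 matrix and fibroblast genes 27 were higher and 0 lower at 24 h (31 and 0 adjusted over the list alone, median 0.656, adjusted p = 4.04e-35), among them Mmp3 (1.62), Dcn (1.26 ± 0.13) and Thbs2 (1.10). Of 39 proliferation genes 16 were higher and 0 lower (28 and 0 adjusted over the list alone, median 0.524, adjusted p = 3.78e-18). The 4 of them with the smallest p, Pcna (0.65), Cdc20 (1.15), Cdk1 (0.73) and Birc5 (0.78), did not pass under median centring (adjusted p = 0.188, 0.0534, 0.0933 and 0.113). Of 30 serum response genes 10 were higher (13 adjusted over the list alone, median 0.472, adjusted p = 1.68e-06), Ccn1 by 1.08 and Egr1 by 1.04 (only these 6 arrays fitted, 0.0746). The unfolded protein response list (2 higher, 4 adjusted over the list alone, median 0.296, adjusted p = 0.00861) did not pass under median centring (0.399) or as deposited (0.174). Of 25 calcium handling genes 3 were lower (4 adjusted over the list alone, median -0.295, adjusted p = 0.000627), with the calcium pump gene Atp2a1 at -1.04. Of 22 energy genes 4 were lower (8 adjusted over the list alone, median -0.346, adjusted p = 0.000273), with Eno3 at -0.92. Of 47 sarcomere genes 1 was higher and 4 lower (1 and 5 adjusted over the list alone, median -0.327, adjusted p = 0.000627), with the fast troponin C gene Tnnc2 at -1.43 ± 0.31, which did not pass with an offset of 1 (0.216). Of 27 myogenic regulators 1 was higher and 4 lower (1 and 6 adjusted over the list alone, median -0.266, adjusted p = 0.00273), with Smarcd3, a chromatin remodelling subunit, at -0.90. The higher member was Smyd1 (1.05, adjusted p = 0.0368), which turned to -0.46 with the mean of its probe sets, whose differences ran from -1.45 to 1.05. It also did not pass without any 1 of 5 of the 6 arrays, the adjusted p between 0.0680 and 0.236, and passed only without ER-MyoD wt replicate 3. Of 14 acetylcholine receptor genes 2 were lower (6 lower and 1 higher adjusted over the list alone, median -0.485, adjusted p = 0.00593), with Chrnd at -1.30 (only these 6 arrays fitted, 0.0884). Cholesterol genes did not pass (median -0.0853, adjusted p = 0.0914) but did under median centring (median -0.278, 0.00216) and as deposited (median -0.150, 0.00279). Smooth muscle markers did not pass (1 higher and 4 lower of 17, median -0.184, adjusted p = 0.0571) but did under median centring (median -0.303, 0.0142) and as deposited (median -0.175, 0.0207).

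Among the fixed genes at 24 h, Id3 (0.95 ± 0.19, adjusted p = 0.00213, and 0.119 with only these 6 arrays fitted) was higher, and Ccnd3 (-0.78, 0.00930) and Hes6 (-0.67, 0.0114) were lower, both not with the mean of probe sets (0.919 and 0.0690). Hes6 also did not pass without ER-MyoD wt replicates 1 (0.0530) or 3 (0.0920), and Cdh15 (-0.55, 0.0498) not without any 1 of the 6 arrays, the adjusted p between 0.0626 and 0.184. Myog was at 3884 ± 516 against 6113 ± 72.8 and did not pass (-0.54 ± 0.22, adjusted p = 0.195), nor did Acta1 (-1.02, 0.132), Chrna1 (-0.97, 0.0786), Mef2c (-0.64, 0.0813), Mylpf (-1.06, 0.169), Tnnt3 (-0.99, 0.174), Actc1, Myh3, Rb1, Cdkn1a, Ckm and Des. The count of 975 was 433 when only the 6 arrays were fitted and 474 under median centring.

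**Figure D3:**
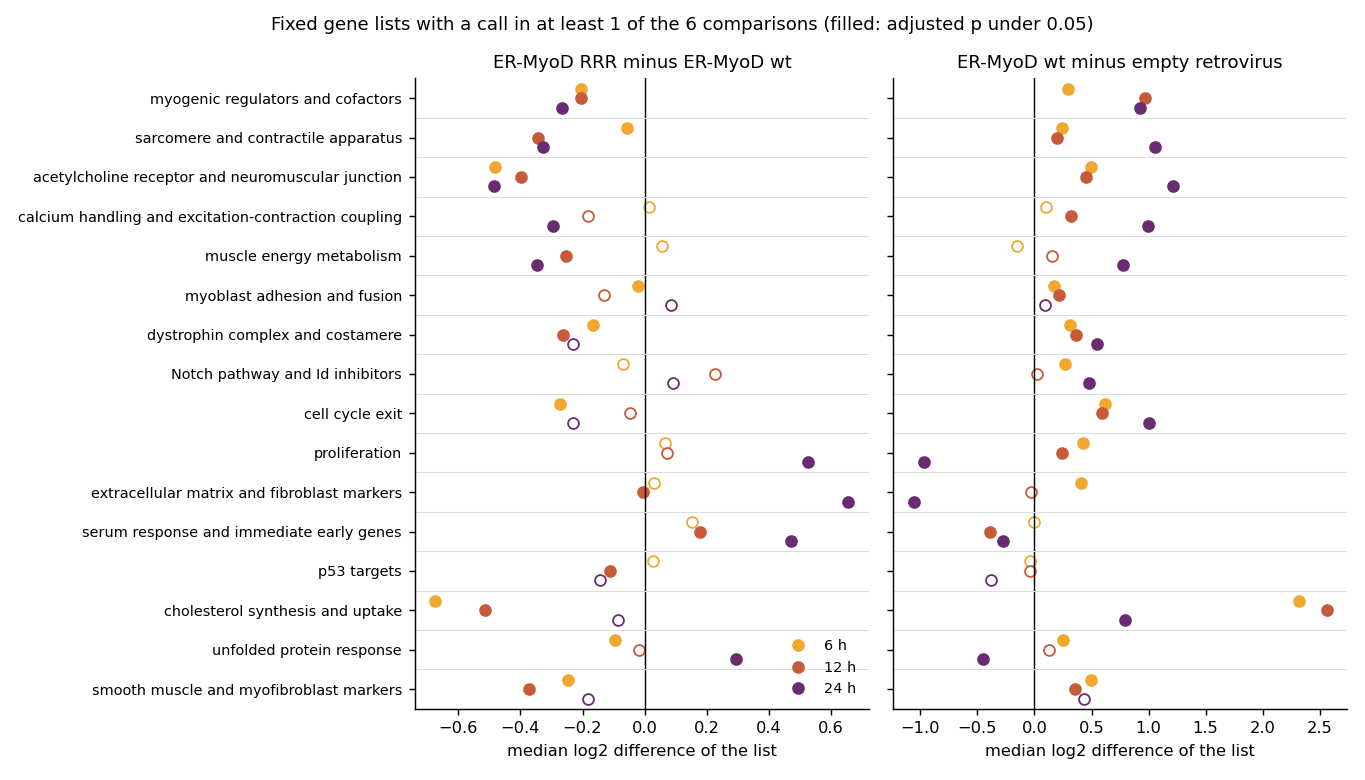
Median log2 difference of 16 fixed gene lists at 6, 12 and 24 h, on the left for ER-MyoD RRR minus wt and on the right for ER-MyoD wt minus empty retrovirus, with filled symbols where the adjusted p was under 0.05 (n = 3 arrays per group). In ER-MyoD RRR minus wt the cholesterol list lies at -0.674, -0.512 and -0.0853 at 6, 12 and 24 h and the matrix list at 0.656 at 24 h.

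Genes that differed between ER-MyoD wt and empty retrovirus at another time were then followed as a set. The 928 genes at least 2-fold higher in ER-MyoD wt than in empty retrovirus at 24 h lay lower in ER-MyoD RRR than in wt at 6 h, with a median of -0.166 (adjusted p = 9.37e-12), 108 of them past the threshold lower and 5 higher. At 12 h their median was -0.284 (adjusted p = 9.04e-26), with 97 lower and 0 higher. At 24 h the 638 genes chosen at 12 h had a median of -0.263 (adjusted p = 7.85e-10), with 92 lower and 27 higher, while their medians against empty retrovirus were 1.10 in ER-MyoD wt and 0.898 in ER-MyoD RRR. The 1215 genes lower in ER-MyoD wt than in the control did not pass at 6 h (median 0.0826, adjusted p = 0.0820), but did in 5 of 12 fits with one array left out. These were the fits without ER-MyoD wt 24 h replicate 3 (adjusted p = 0.0179), ER-MyoD RRR 6 h replicate 3 (0.0248), empty retrovirus 24 h replicates 1 (0.0377) or 2 (0.0490), or ER-MyoD wt 6 h replicate 1 (0.0424). These genes were higher in ER-MyoD RRR at 12 h (median 0.254, adjusted p = 1.44e-21). The 514 chosen at 12 h were higher at 24 h (median 0.336, adjusted p = 1.46e-20). All calls held with an estimated correlation, the largest adjusted p = 0.000254. The 24 h median of the higher genes was -0.105 and did not pass (adjusted p = 0.214) for genes chosen in ER-MyoD RRR minus empty retrovirus instead. The 6 h median of the lower genes was 0.219 and passed for genes that passed at both other times.

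**Figure D4:**
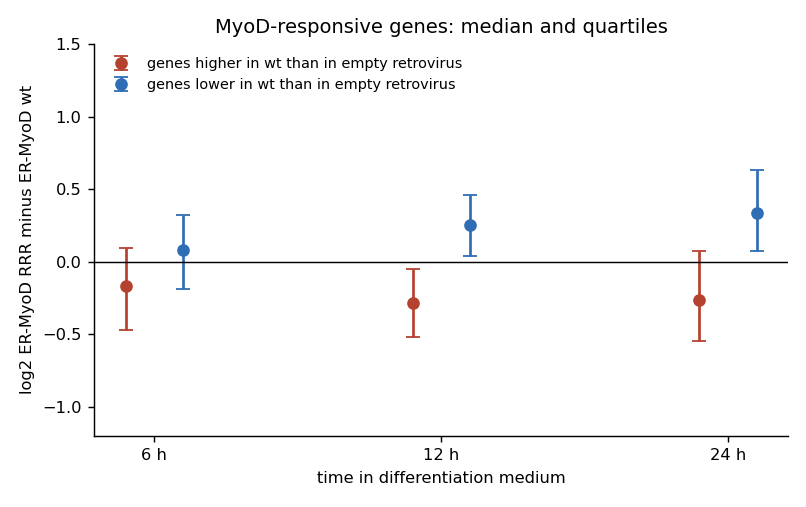
Log2 difference of ER-MyoD RRR minus wt at 6, 12 and 24 h for genes at least 2-fold higher or lower in ER-MyoD wt than in empty retrovirus at another time, as median (point) and quartiles (bar) over genes. The medians of the higher genes lie at -0.166, -0.284 and -0.263 and those of the lower genes at 0.0826, 0.254 and 0.336.

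ER-MyoD RRR was also compared with empty retrovirus. At 24 h Tnnt2 rose by 8.54, Mymk by 7.91, Myog by 7.10 ± 0.22 (adjusted p = 5.05e-19) and Actc1 by 6.94, while Dkk2 (-3.73), C1s1 (-3.15), Fat4 (-3.11) and Pdgfra (-3.03) fell. The totals were 1304 genes higher and 1200 lower at 6 h, 922 and 898 at 12 h and 1548 and 1894 at 24 h. Under median centring they were 1444 and 700, 1034 and 340, and 923 and 1743.

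At 6 h 7 of 47 sarcomere genes rose (8 adjusted over the list alone, median 0.193, adjusted p = 0.0122). So did 11 of 25 Notch pathway genes (13 rose and 1 fell adjusted over the list alone, median 0.742, adjusted p = 8.01e-05) and all 19 cholesterol genes (19 adjusted over the list alone, median 1.34, adjusted p = 9.31e-31), Fdft1 by 2.34. Of 17 smooth muscle markers 7 rose (9 adjusted over the list alone, adjusted p = 2.08e-07), Tagln by 3.87. Of 39 proliferation genes 19 rose and 1 fell (20 and 4 adjusted over the list alone, adjusted p = 1.23e-06). Cell cycle exit genes passed (adjusted p = 0.0141). The fusion list (0.0180) had an adjusted p = 0.157 with an estimated correlation and 0.0531 and 0.0604 without ER-MyoD RRR replicate 1 or empty retrovirus replicate 3, and the matrix list (0.00422) an adjusted p = 0.142 with an estimated correlation. The myogenic and acetylcholine receptor lists did not pass at 6 h (adjusted p = 0.0829 and 0.268). At 12 h 12 of 27 myogenic regulators rose (13 adjusted over the list alone, median 0.633, adjusted p = 1.55e-09), Myog by 2.98 ± 0.22. All 19 cholesterol genes rose (19 adjusted over the list alone, median 2.09, adjusted p = 4.1e-53). So did 9 of 25 Notch genes with 1 lower (10 and 3 adjusted over the list alone, adjusted p = 0.000513) and 8 of 17 cell cycle exit genes (8 adjusted over the list alone, adjusted p = 9.42e-07). Of 47 sarcomere genes 8 rose (8 adjusted over the list alone). Their mean of 0.362 and the test pointed up (adjusted p = 0.0325), while the median was -0.0015 and 0.0909 under median centring. The list did not pass there (0.112) or without empty retrovirus replicate 3 (0.0849). Fusion (0.00697), proliferation (0.00135) and the lower serum response list (0.0319) had an adjusted p = 0.116, 0.153 and 0.0923 with an estimated correlation, and the fusion median of 0.103 was -0.0117 as deposited. Serum response did not pass as deposited (0.0565) or without empty retrovirus replicate 3 (0.0751).

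At 24 h 22 of 47 sarcomere genes rose and 2 fell (24 and 3 adjusted over the list alone, median 0.854, adjusted p = 7.92e-15). Calcium genes rose, 12 of 25 (13 adjusted over the list alone, median 0.889, adjusted p = 1.21e-08), and so did 10 of 22 energy genes (11 adjusted over the list alone, median 0.540, adjusted p = 1.84e-08). Of 27 myogenic regulators 16 rose and 1 fell (16 and 1 adjusted over the list alone, median 0.873, adjusted p = 2.86e-11). Of 39 proliferation genes 2 rose and 16 fell (2 and 17 adjusted over the list alone, median -0.343, adjusted p = 1.54e-06). Of 35 matrix genes 6 rose and 13 fell (6 and 14 adjusted over the list alone, median -0.278, adjusted p = 0.00178), with an adjusted p = 0.108 with an estimated correlation. Of 26 interferon genes 1 rose and 10 fell (1 and 11 adjusted over the list alone, median -0.618, adjusted p = 0.00161), Ifit3 by -2.44 ± 0.42, Rtp4 by -1.54 and Gbp3 by -1.45. Of 20 p53 targets 2 rose and 8 fell (3 and 11 adjusted over the list alone, adjusted p = 0.0442), with an adjusted p = 0.0552 with an estimated correlation and 0.0886, 0.0549 and 0.0583 without empty retrovirus replicates 1 or 3 or ER-MyoD RRR replicate 1. Cholesterol (adjusted p = 1.34e-07), acetylcholine receptor (1.66e-07), Notch (0.000201), cell cycle exit (0.00191) and dystrophin (0.00577) lists were higher and the unfolded protein response list lower (0.0016).

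**Figure D5:**
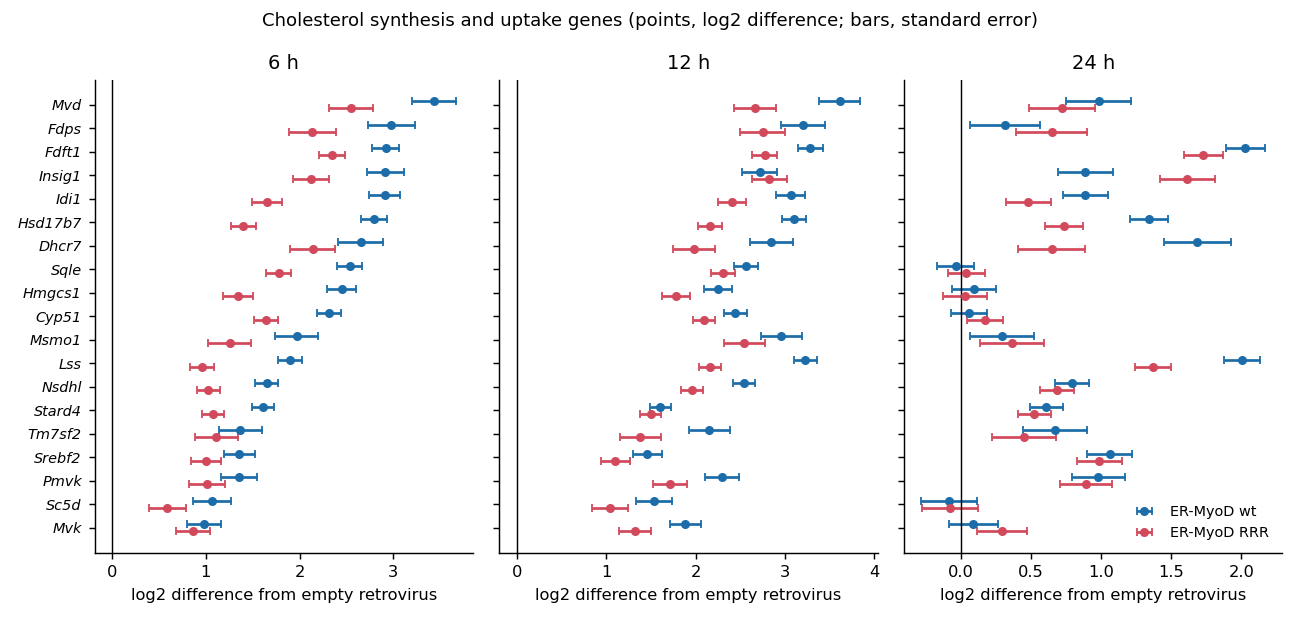
Log2 difference from empty retrovirus of the 19 measured cholesterol genes at 6, 12 and 24 h for ER-MyoD wt and ER-MyoD RRR, with standard errors (n = 3 arrays per group). The medians are 2.32, 2.56 and 0.793 in ER-MyoD wt and 1.34, 2.09 and 0.644 in ER-MyoD RRR.

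The time course of ER-MyoD wt against its own 0 h arrays mixes medium, hormone and MyoD. Another cell preparation at 0 h may enter as well, since genes of the Y chromosome differed from 0 h too, as given at the end. From 0 to 24 h, 2634 genes rose and 2947 fell. Mymk (8.14), Myog (7.92 ± 0.22, adjusted p = 2.86e-20), Chrng (7.64), Tnni1 (7.23) and Stac3 (6.29) rose most, and the growth factor targets Ccn2 (-6.83), Dusp6 (-4.65), Myc (-4.35), Etv4 (-4.34) and Ier3 (-4.30) fell most. Of 30 serum response genes 0 rose and 25 fell by 6 h (1 and 25 adjusted over the list alone, median -2.16, adjusted p = 7.08e-28). By 24 h 1 rose and 25 fell (1 and 25 adjusted over the list alone, median -2.42, adjusted p = 1.95e-19). Of 39 proliferation genes 15 rose and 0 fell at 6 h (15 and 0 adjusted over the list alone, median 0.344, adjusted p = 5.97e-08). At 24 h 0 rose and 38 fell (0 and 38 adjusted over the list alone, median -2.09, adjusted p = 2.5e-32), Mcm5 by -3.25. Cholesterol genes rose from 13 of 19 at 6 h (14 adjusted over the list alone, median 0.973, adjusted p = 5.35e-16) to 19 at 24 h (19 adjusted over the list alone, median 2.10, adjusted p = 1.95e-23). Sarcomere genes rose at 24 h, 24 of 47 with 2 lower (24 and 2 adjusted over the list alone, median 0.780, adjusted p = 6.8e-09). Smooth muscle markers fell, 8 of 17 with 1 higher at 24 h (8 and 1 adjusted over the list alone, median -0.519, adjusted p = 0.00166), Tagln by -3.61.

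Whether the ER-MyoD RRR minus wt difference itself changed from 6 h to 24 h was tested directly. It rose for 243 genes and fell for 127. The difference of Timp3, an inhibitor of matrix proteases, rose by 2.05 ± 0.20 (adjusted p = 1.02e-06), of the periostin gene Postn by 1.89 ± 0.17 and of Lox, which crosslinks collagen, by 1.85. That of Mki67, a marker of dividing cells, rose by 1.96 ± 0.36, and of the growth factor gene Igf1 by 1.95 ± 0.30. The difference of Hoxb5 fell by 2.27 ± 0.46 (adjusted p = 0.00616). The matrix list rose (9 of 35 members, 19 adjusted over the list alone, median 0.526, adjusted p = 7.9e-22). So did proliferation (7 of 39, 15 adjusted over the list alone, median 0.479, adjusted p = 8.64e-14) and cholesterol synthesis (6 of 19, 10 adjusted over the list alone, median 0.514, adjusted p = 3.18e-10). The energy list fell (1 of 22, 2 adjusted over the list alone, median -0.369, adjusted p = 0.00622) and did not pass without the 3 arrays that stood apart (0.0704). Under median centring 49 genes passed, 26 higher and 23 lower, and when only the 12 arrays concerned were fitted 134 did.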

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

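The tests of the lists in the change from 6 h to 24 h, of the delay among MyoD-responsive genes alone, of the share of responding cells, of the cholesterol genes and of the size of the Y-linked differences, and the redrawn residuals for the delay, were chosen only after the result was seen.

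The difference between ER-MyoD RRR and wt was itself different at 24 h and 6 h for 370 genes. Beside the genes named in the report, the change was 1.94 ± 0.30 for Aspn, which encodes a small matrix proteoglycan, 2.05 for Timp3, 1.95 for Igf1, 1.96 for Mki67, -2.27 for Hoxb5, -1.93 ± 0.42 for the calcium-binding protein gene S100a8, -1.93 ± 0.43 for Tnnc2, -1.93 ± 0.48 for Pla2g3, -2.05 ± 0.52 for Klhl10 and 2.08 ± 0.52 for Cd33. Cd33, Klhl10 and Pla2g3 did not pass under median centring (adjusted p = 0.0820, 0.0777 and 0.0794), nor when single arrays were left out (8, 8 and 5 of 12 arrays). Tnnc2 did not pass with an offset of 1 (0.135) or without ER-MyoD RRR 6 h replicate 1 (0.0520), and S100a8 not when only the groups compared were fitted (0.0538). Of the fixed lists, the median change was 0.526 for matrix genes, 0.479 for proliferation, 0.514 for cholesterol synthesis, 0.430 for the unfolded protein response (4 of 21 genes, 9 adjusted over the list alone, adjusted p = 9.29e-06), 0.197 for fusion (adjusted p = 0.00126, and 0.0575 with an estimated correlation), 0.199 for serum response (0.0146, and 0.0575 with an estimated correlation), -0.369 for energy metabolism and -0.466 for calcium handling (0.0117). Serum response did not pass without the 3 arrays that stood apart (0.180) or without ER-MyoD wt 24 h replicate 3 (0.0567), ER-MyoD RRR 6 h replicate 2 (0.116) or ER-MyoD wt 6 h replicate 2 (0.0753), and calcium handling not without that last array (0.0582). Of 100 splits drawn from 200, 2 had as many genes past the threshold, the real one included. These splits also mix the constructs at each time, so they do not test the change by itself and do not exclude chance. The highest other gave 1233 genes. It turns round the arrays of one time point and so adds the 2 differences, a structure of the samples, and the next highest gave 364.

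In each of the 12 comparisons of 3 arrays against 3, the real split was the 1 of 10 with as many genes, and 10 splits are too few for a share under 0.05. For ER-MyoD RRR minus wt at 6, 12 and 24 h the real counts were 668, 319 and 975 and the highest others 23, 1 and 16. For ER-MyoD wt minus empty retrovirus they were 2302, 2788 and 4604 against 1, 2 and 1, for ER-MyoD RRR minus empty retrovirus 2504, 1820 and 3442 against 1, 0 and 1, and for ER-MyoD wt against 0 h 3216, 3696 and 5581 against 0, 1 and 1.

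Genes higher in ER-MyoD wt than in empty retrovirus lay lower in ER-MyoD RRR than in wt at all 3 times. A delay along the wild-type course cannot be told apart from a lower level of response: of the MyoD-responsive genes nearer to the control 25 of 202 (12.4%, interval over genes 8.53 to 17.6) lay beyond every wild-type time in the same direction. That interval counts genes as independent and leaves out the spread between arrays. Of all genes at 24 h it was 117 of 975 (12.0%), against at most 5.13% in 100 fits of redrawn residuals without such genes. In that highest fit 2863 genes passed and 147 lay beyond every wild-type time, so by count the redrawn fits reached the observed number. The bound of 10% set beforehand also took in genes outside the response and ignored that no array fell between 12 and 24 h. Less ER-MyoD RNA in the mutant stays open: without ER-MyoD RRR 6 h replicate 2, whose Myod1 signal was 310, the median at 6 h was -0.189 (adjusted p = 3.33e-09), but the interval of the Myod1 difference then ran from -0.31 to 0.99, and protein was not measured. A smaller share of responding cells may also contribute: 7 of 209 genes (3.35%) lay further from the control in ER-MyoD RRR than in wt, but the same ER-MyoD wt 24 h arrays enter both differences. Of 240 genes chosen at 12 h alone, 30 (12.5%) differed in ER-MyoD RRR minus wt at 24 h in the direction of wt minus empty retrovirus at 12 h. That count does not use the empty retrovirus arrays at 24 h, so it does not show which genes lay further from the control then.

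Cholesterol genes were higher in both ER-MyoD groups than in empty retrovirus cells. Empty retrovirus cells left without the change of medium are argued against only if they started at the ER-MyoD wt level of 0 h. No empty retrovirus array at 0 h was analysed to show that. In ER-MyoD wt 25 serum response genes fell by 6 h, with a median of -2.29. Their median in ER-MyoD wt minus empty retrovirus was -0.207 (quartiles -0.937 to 0.246), far from the fall that would then be left. A response graded with the construct stays open: 19 of 19 genes had ER-MyoD RRR between empty retrovirus and wt at 6 h, which repeats the lower list that prompted the test, and 12 of 19 did at 24 h, where 7 lay above wt. In ER-MyoD wt the median rise from 0 h to 6 h, given above, was smaller than the median difference of 2.32 from empty retrovirus at 6 h. At 24 h the rise from 0 h was the larger, the difference from empty retrovirus being 0.793. The gap therefore also holds the level of the empty retrovirus cells, which had no 0 h arrays. Whether the hormone-bound fusion protein, the MyoD program or growth of the cultures contributed stays open, since no array had the receptor part alone.

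A set of 61 genes differed between ER-MyoD RRR and wt the same way at all 3 times, 34 higher and 27 lower, where independent lists would share 0.0884 and 0.0646. Most of them also differed between ER-MyoD wt and empty retrovirus: 54 of 61 (88.5%) did so in the opposite direction at 12 h and 24 h. Since ER-MyoD wt arrays enter both differences, the 107 genes that differed the same way at 6 h and 12 h were also set against 24 h, where 90 (84.1%) were opposite and 5 the same. A lasting difference of the ER-MyoD wt cells apart from MyoD would leave the same pattern at every time. These values therefore do not tell it from the MyoD response. A male preparation against a female one is argued against: 0 of 4 measured sex-linked genes were in the set, and the intervals of Eif2s3y reached at most 1.10, 0.76 and 0.88 at 6, 12 and 24 h, where a fall to its lowest array would be 1.41, 1.27 and 2.11. A different mix of the sexes cannot be told apart from the construct, since the largest Y-linked difference (Eif2s3y at 6 h, 0.579 without its sign, adjusted p = 0.238) had an interval from -1.10 to -0.06.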

How the results depend on the processing

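Values as deposited, the 3 arrays that stood apart left out, and lists under other scalings were chosen after seeing the data. Of 975 calls of named genes, those left were 852 under median centring, 938 as deposited, 945 without the 3 arrays that stood apart, 840 with only the groups compared in the fit, 867 with the mean of all probe sets, 936 and 964 with offsets of 1 and 64, 937 without the trend, 969 with robust moderation and 968 with arrayWeights. Of 133 list calls, 107 were left with an estimated correlation, 133 with fry, 127 under median centring, 128 as deposited and 126 without the 3 arrays. Newly called were 0, 70, 10, 7 and 3 lists. Among those new under both median centring and as deposited were smooth muscle in ER-MyoD RRR minus wt at 24 h (0.0142 and 0.0207), calcium handling at 12 h (0.0403 and 0.0468), and the unfolded protein response at 12 h, higher in ER-MyoD wt (0.0216 and 0.0287) and in ER-MyoD RRR (0.0327 and 0.0346) than in empty retrovirus. New without the 3 arrays were serum response (0.0420) at 6 h and interferon (0.0283) at 24 h in ER-MyoD RRR minus wt, and energy in ER-MyoD wt minus empty retrovirus at 12 h (0.0178). With one array left out, 5512 of 6102 gene calls and 810 of 846 list calls held. Where no cause is given, the cause was not tested.

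Counts of ER-MyoD RRR minus wt at 6 h (668) were 106 with only the groups compared, 254 under median centring, 1047 with arrayWeights, 134 with a 2-fold limit and 281 to 727 with one array left out. At 12 h (319) they were 130 under median centring, 578 with arrayWeights, 491 without the 3 arrays, 110 with a 2-fold limit and 151 to 224 with one array left out. At 24 h (975) they were 433 with only the groups compared, 474 under median centring, 228 with a 2-fold limit and 655 to 839 with one array left out. The change from 6 h to 24 h (370) gave 134, 49, 598 (arrayWeights) and 182 genes under the same settings. A 2-fold limit left 920, 1152 and 2143 genes of ER-MyoD wt minus empty retrovirus, 861, 680 and 1308 of ER-MyoD RRR minus empty retrovirus, and 1048, 1405 and 2858 of ER-MyoD wt against 0 h. Only the groups compared gave 1591 for ER-MyoD RRR minus empty retrovirus at 6 h. Testing all probe sets, which counts more features, gave 7573 for ER-MyoD wt and 5374 for ER-MyoD RRR minus empty retrovirus at 24 h, 3917 for the latter at 6 h and 9170 for ER-MyoD wt from 0 to 24 h.

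Fry, which tests each list without comparing it to other genes, called 14 lists for ER-MyoD RRR minus wt at 24 h (9 in camera), 18 and 21 for ER-MyoD wt minus empty retrovirus at 12 and 24 h, 18 and 16 for ER-MyoD RRR minus empty retrovirus at 6 and 12 h (5 at 12 h with an estimated correlation), and 15 and 18 for ER-MyoD wt from 0 h to 6 and 24 h. The MyoD-lowered genes at 6 h had a median of 0.219 when past the threshold at both other times, and 0.0586 to 0.102 with one array left out, where 5 of 12 fits passed. The MyoD-raised genes at 24 h had a median of -0.105 when chosen in ER-MyoD RRR. With the mean of all probe sets 4 named genes reversed, as their probe sets differ: Smyd1 in ER-MyoD RRR minus wt at 24 h (1.05 to -0.46), and in ER-MyoD RRR minus empty retrovirus Edem1 (-0.42 to 0.19) and Vcl (0.46 to -0.0887) at 6 h and Plk2 (-0.66 to 0.0582) at 12 h.

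The replicate number as a block gave 781, 355 and 1075 genes for ER-MyoD RRR minus wt, 2440, 2938 and 4760 for ER-MyoD wt and 2674, 1926 and 3578 for ER-MyoD RRR minus empty retrovirus at 6, 12 and 24 h, 3397, 3812 and 5690 from 0 h, and 491 for the change. Deviations of arrays with the same number correlated between -0.106 and 0.0921, and 12 of 36 matched best with their own number. These correlations gave no sign of pairs, but every count rose with the block, so a small shared part is not excluded. Of named genes 972 of 975 calls and of lists 132 of 133 held under it. Signals near background limit what low genes can show.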

Other observations

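The 7 lists of other cell types did not pass in any of the 13 comparisons under the main setting. The lowest adjusted p was 0.0726 for endothelial markers in ER-MyoD RRR minus empty retrovirus at 24 h (median 0.277, 3 of 15 higher, and 3 adjusted over the list alone), and that list passed under median centring (median 0.263, adjusted p = 0.0236) but had an adjusted p = 0.222 with an estimated correlation. The lowest was 0.274 for epithelial, 0.325 for cardiac, 0.337 for neuronal and glial, 0.345 for macrophage and blood, 0.412 for adipocyte, and 0.652 for chondrocyte and osteoblast markers. Single members moved: Nes, an intermediate filament gene of neural and muscle progenitors, rose in ER-MyoD wt minus empty retrovirus by 2.34 ± 0.34 at 6 h and 3.72 at 24 h, and Csf1r, a receptor of macrophages, by 1.39 ± 0.19 at 6 h, 1.86 at 12 h and 0.64 at 24 h (adjusted p = 0.0127, and 0.0578 without the 3 arrays that stood apart). Estrogen-responsive genes, of interest because the fusion carries the estrogen receptor, had their lowest adjusted p at 0.164 (ER-MyoD RRR minus wt at 6 h, 1 of 14 higher, and 4 with 1 lower adjusted over the list alone). The acetyltransferases, deacetylases and partners of MyoD had theirs at 0.217 (ER-MyoD RRR minus empty retrovirus at 6 h), although Hdac11, a histone deacetylase gene, rose by 2.66 in ER-MyoD wt minus empty retrovirus at 24 h. Interferon genes did not pass in ER-MyoD wt minus empty retrovirus at 24 h (1 rose and 7 fell, 1 and 7 adjusted over the list alone, median -0.409, adjusted p = 0.0928), but did under median centring (median -0.422, adjusted p = 0.0386).

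The earlier wild-type time points against 0 h were also read by list. At 6 h Dll1 rose by 3.33 and Zbtb18 by 3.43, while Cited2 (-3.52), Id3 (-2.80), Egr1 (-3.41) and the matrix signal gene Ccn2 (-5.09) fell. Myogenic regulators (9 of 27 rose, 10 adjusted over the list alone, adjusted p = 0.000105), cell cycle exit genes (0.000419) and acetylcholine receptor genes (0.00757) were higher, as was fusion (0.00786, and adjusted p = 0.120 with an estimated correlation). Smooth muscle markers were lower (0.0417, and adjusted p = 0.0557 with an estimated correlation), and not without ER-MyoD wt 6 h replicates 2 (0.0645) or 3 (0.0666) or ER-MyoD wt 0 h replicate 3 (0.0594). At 12 h Myog rose by 4.68 and Mymk by 6.91. Myogenic regulators (14 rose and 1 fell, 15 and 2 adjusted over the list alone, adjusted p = 1.64e-08), cell cycle exit (5.58e-07), cholesterol (2.58e-30) and acetylcholine receptor genes (0.000419) were higher, and serum response (3.7e-30) and smooth muscle genes (7.79e-05) lower. Proliferation (5.85e-05), fusion (0.0259), calcium (0.0252) and the lower matrix list (0.000419) had an adjusted p = 0.0788, 0.1998, 0.0632 and 0.0716 with an estimated correlation. Calcium did not pass without ER-MyoD wt 12 h replicate 1 (0.0947), nor the higher sarcomere list (0.0324) without ER-MyoD wt 12 h replicate 2 (0.0628), nor the higher p53 targets (0.0324) under median centring (0.0980) or as deposited (0.0737). At 24 h calcium (6.62e-08), energy (3.54e-07), acetylcholine receptor (5.5e-07), myogenic (1.69e-09) and cell cycle exit genes (0.000313) were higher, and matrix genes lower (0.0082, and adjusted p = 0.185 with an estimated correlation).

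Among the 61 genes that differed between ER-MyoD RRR and wt at all 3 times, several were chosen for naming after their values were seen. The chemokine genes Ccl2 (1.07, 1.45 and 1.36 at 6, 12 and 24 h) and Ccl7 (1.18, 1.25 and 1.49), the arachidonate pathway gene Alox5ap (1.01, 1.38 and 1.29) and Tgfbr3, a coreceptor of transforming growth factor beta (0.85, 0.97 and 1.34), were higher in ER-MyoD RRR, and the transferrin receptor gene Tfrc (-0.77, -0.65 and -0.99) was lower. The 7 MyoD-responsive genes further from empty retrovirus in ER-MyoD RRR than in wt at 24 h, also named after their values were seen, were Aldh1a1, Mest, Stc1, Gfra1, Daam1, Meg3 and Insig1. The Insig1 difference (0.73, adjusted p = 0.0228) did not pass under median centring (0.51, adjusted p = 0.281), nor without ER-MyoD wt 24 h replicate 3 (0.0925) or ER-MyoD RRR 24 h replicates 2 (0.0638) or 3 (0.0884). Aldh1a1 did not pass with an offset of 1 (0.0582) or when only the groups compared were fitted (0.0584), and the other 5 were not tried under the alternatives.

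The probe sets chosen for Ckm and Des, genes of muscle creatine kinase and desmin, stayed near the same signal in all groups, while another probe set of each did not. The other Ckm probe set differed by -1.25 (adjusted p = 0.0720) and the other Des probe set by -1.21 (adjusted p = 0.0937) in ER-MyoD RRR minus wt at 24 h.

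Sex-linked genes differed between some groups, and the comparisons given here were picked out after their values were seen. In ER-MyoD wt the 3 measured genes of the Y chromosome rose from 0 to 24 h, Eif2s3y by 1.47 ± 0.25 (adjusted p = 3.23e-05), Kdm5d by 0.99 ± 0.22 (0.000588) and Uty by 1.15 ± 0.26 (0.000945). They passed at 6 h as well (0.0353, 0.0387 and 0.0152), but at 12 h only Kdm5d (0.0309) and Uty (0.0175) did, and not Eif2s3y (0.39, adjusted p = 0.336). In ER-MyoD RRR minus empty retrovirus Eif2s3y was lower at 6 h (-1.10, adjusted p = 0.00312) and Kdm5d at 24 h (-0.77, 0.0117). None of the 3 passed in ER-MyoD RRR minus wt or in ER-MyoD wt minus empty retrovirus at any time, and Xist passed in none of the 13 comparisons. Whether the 0 h arrays came from another cell preparation was not tested.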
